A study of Mus musculus with 4 samples.

How the data were processed

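Total RNA from the small intestine of 4 mice, each 1 month old, was labelled with biotin and hybridised to Affymetrix oligonucleotide arrays, 1 array per mouse. Per the labels, RNA was isolated with a Qiagen RNeasy mini kit and labelled by the manufacturer's usual procedure. The labels do not say which part of the small intestine was taken or whether epithelium was separated from the rest of the wall. Both null animals carried an HNF4 allele with loxP sites over a minus allele together with villin-Cre, which is active in the intestinal epithelium. The labels name HNF4 without saying which of the paralogues Hnf4a and Hnf4g was targeted. Animal 190 was male and animal 278 female. Among the controls, animal 277 was a female with a loxP allele over a wild-type allele and villin-Cre, and animal 191 was a male with a loxP allele over a minus allele and no Cre. Sex and genotype therefore cannot be told apart between the controls. The labels name 4 separate animals. Their numbers are adjacent within each sex across the groups, 190 with 191 and 278 with 277. The labels do not say whether any were littermates, so sex cannot be told apart from what adjacent numbers may stand for.

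The deposited table holds 1 intensity per probe set and array on a linear scale. The software that summarised the probes, its background correction and its scaling are not given in the sources used here, so whether the arrays had been scaled to a common target is unknown. Values ranged from below 0, for 1.42% to 2.46% of probe sets per array, to between 10184 and 11137 at the top. Median deposited intensities were 43.2 in null 190, 53.3 in null 278, 50.2 in control 277 and 49.5 in control 191. No pair of arrays held identical values, and Pearson correlations between arrays after normalization, across probe sets, were 0.927 for the 2 null animals, 0.963 for the 2 controls and 0.941 to 0.96 for the other pairs. Null 190 had the 3 lowest of these correlations (0.927, 0.941 and 0.946), the lowest median and the largest share of values below 0, and it was kept as planned. The deposited values carry no detection calls or probe intensities, so the precision of single values is unknown. That of a comparison rests on the few arrays and on the variance estimated across all probe sets.

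Probe sets were named through the platform annotation, with symbols checked through Entrez identifiers against a gene table of assembly GRCm38.p6. The probe positions were not analysed here, so no coordinates are given and the table served for names and for which genes neighbour each other. Of 22690 probe sets, 64 were controls, 20380 had 1 gene, 691 had several and 1555 had none in the annotation used. No symbol needed an update, and for 29 probe sets the identifier was not matched. The named probe sets covered 12393 genes. Probe sets with several genes or none were tested and counted but not named.

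The test, the samples, the covariates, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule for normalization was part of that plan. Array medians on the scale of log2(intensity + 16) differed by 0.23, above the limit of 0.2 set beforehand, so intensities were quantile normalized between arrays, set to at least 0 and taken to log2 after adding 16. Differences on this scale understate the change of dim probe sets. The dimmest 30% of probe sets by mean over the 4 arrays were left out, which kept 15838 of 22626 probe sets that were not controls. Of these, 1412 had no gene or several, and the rest covered 9546 genes. Null and control arrays were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with an intensity trend in the prior, without covariates, in a two-sided test with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior worth 4.65. Standard errors and 95% intervals are those of the moderated fit. A gene was represented by its probe set with the highest mean. With 2 animals per group, the difference within the male pair and within the female pair is given beside the difference over all 4 arrays.

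Of 33 gene lists fixed beforehand, the 30 with at least 5 members among the genes tested were compared with all other genes by limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Over all lists, 433 members had a probe set of their own, counted before the filter on dim probe sets. Only those that passed the filter were tested, and members counted below are these alone. The 2 symbols Nherf1 and G6pc1 were matched by hand to their older forms Slc9a3r1 and G6pc. The test was also run with a correlation estimated for each list, where camera works with the 2 residual degrees of freedom of the fit. With so few, hardly any list can pass after adjustment over 30 lists. A call lost in that run therefore does not show that correlation between genes had produced it. Counts described as adjusted over the list alone use Benjamini-Hochberg adjustment within 1 list.

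The genes named are Hnf4a and Hnf4g, then up to 12 genes higher and 12 lower in the null animals among those past the threshold with the same direction in both pairs, with remaining places filled by the smallest p and given as values. From each list they include up to 4 members past the threshold or, where there were none, the 2 members with the smallest p, again as values. Genes that mark sex and the control probe sets for the ends of the Actb and Gapdh transcripts complete the rule. Any other gene named was chosen after its value was seen.

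Alternatives were a pseudocount of 1 or 64, the intensities as deposited, centring of each array on its median, no filter or one of 50% on dim probe sets, sex as a block, no trend in the prior, array weights, an adjusted p under 0.1, an added limit of 1.5-fold, the mean of all probe sets of a gene, each other probe set of a named gene, the estimated correlation, and leaving out each array in turn. No alternative was added later.

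The fit and the list test were checked on simulated arrays with the real probe sets' mean levels, in 10 simulations of 15838 probe sets each. With each probe set's spread drawn from the fitted prior, limma recovered 6.12% of planted log2 changes of 1, 76% of changes of 2 and 98.5% of changes of 4, and 5.06% of its calls were false. Spreads had at first been set to the moderated variances, and the draw from the prior was added after that result was seen. With moderated variances the recovered shares were 36.7%, 99.3% and 100%, and 11% of calls were false, above the nominal 5%. The list test called 2 of 300 unshifted lists with the prior and 3 of 300 with the moderated variances, and in both it recovered 49 of 50 lists shifted by 0.5. Members of a list were simulated as independent, so these figures do not cover lists whose members move together. The planted shift of 0.5 also exceeds the median of every list tested on the real arrays, of which −0.40 was the farthest from 0. The recovery of smaller shifts was not simulated.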

Results

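Gene expression was measured in small intestine from 2 mice labelled HNF4 null and 2 controls, all 1 month old, with 1 male and 1 female in each group. HNF4 is a nuclear receptor family of liver and gut epithelium, and villin-Cre was used to remove its floxed allele from intestinal epithelium. Each animal gave 1 array of 22626 probe sets apart from controls, of which 15838 were bright enough to test. Signal at the 3' end over the 5' end was 1.3 to 1.47 for Actb and 0.929 to 0.988 for Gapdh, so the ratio overlapped between the groups. Xist, expressed from the inactive X chromosome, had deposited intensities of 389 and 489 (488.5 before rounding) in the 2 animals labelled female and 1.12 and 1.79 in the 2 labelled male. The Y-linked gene Eif2s3y gave 61.1 and 147 in the males and 1.12 and −2.23 in the females, and 2 further Y-linked genes, Kdm5d and Uty, were brighter in both males on the probe sets that passed the filter.

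The transcript of the targeted gene family was not lower in the animals labelled null. All 4 Hnf4a probe sets had a null minus control log2 difference above 0, from 0.08 to 0.32. The brightest of them measured 10.10 ± 0.10 in the null animals and 9.87 ± 0.45 in the controls (SD, n = 2 each), on the scale of log2(intensity + 16). Its difference of 0.23 had a 95% interval from −0.30 to 0.77 and an adjusted p of 1 in limma. The difference was 0.62 in the male pair and −0.16 in the female pair. The male control, which carried 1 minus allele without Cre, was the lowest of the 4 arrays at 9.55. Both null animals carried a minus allele too and read 10.17 and 10.03, so the minus allele alone does not account for that low value. Without that control the median over the 4 probe sets was −0.046. Hnf4g, the paralogue expressed in gut epithelium, differed by 0.16 with a standard error of 0.21 on its brighter probe set and by 0.12 on the other, both with an adjusted p of 1 in limma. The part of the gene that was deleted, and whether these probe sets lie within it, are not given in the sources used here, so the values do not check the null labels.

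**Figure D1:**
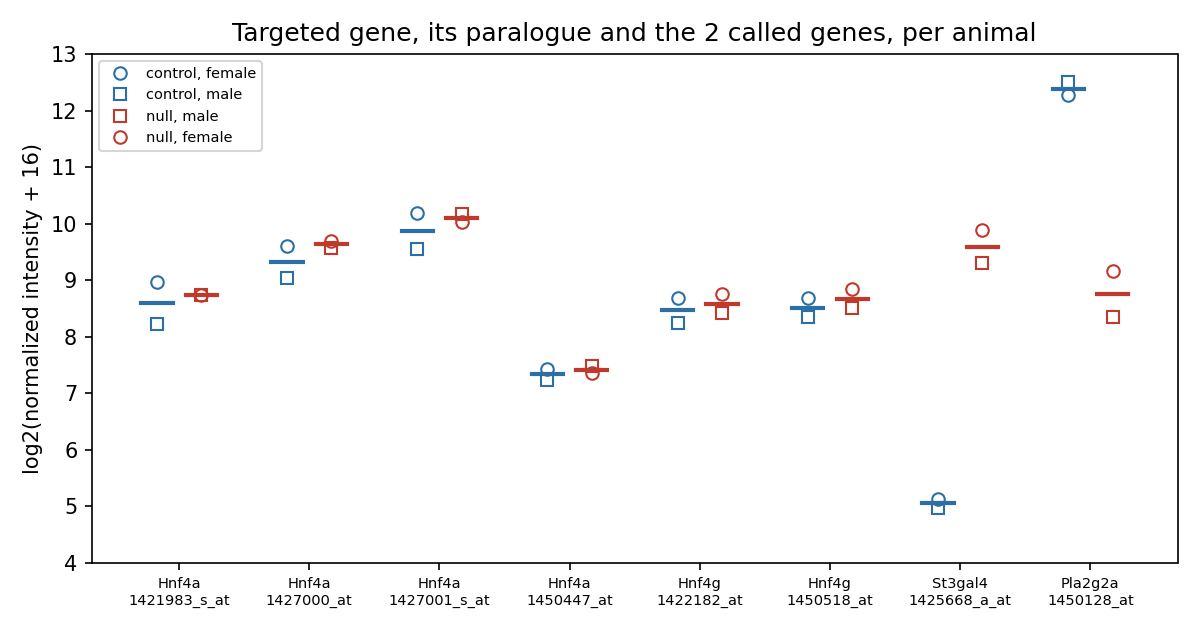
Normalized intensity on the scale of log2(intensity + 16) for each animal, by probe set. Symbols are single animals, squares for males and circles for females, and bars are group means of 2 animals. Null and control animals overlap or lie close together for Hnf4a and Hnf4g and lie apart for St3gal4 and Pla2g2a.

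The comparison of null with control intestine asks which transcripts depend on HNF4 in the epithelium. Of all probe sets tested, 2 passed the threshold. St3gal4, a sialyltransferase of the Golgi, rose by 4.54 on the log2 scale (SE 0.26, 95% interval 3.92 to 5.16), with an adjusted p of 0.013 in limma. Its deposited intensities were 600.1 and 923 in the null animals against 19.2 and 15.8 in the controls, which is as dim as the Y-linked Kdm5d in the females (13.9 and 18.3). The controls are thus not shown to lie above background, no fold is given, and the size depends on the pseudocount: the log2 difference of St3gal4 was 5.39 with a pseudocount of 1 and 3.33 with 64. Pla2g2a, a secreted phospholipase of Paneth cells, fell by 3.63 on the log2 scale (SE 0.26, 95% interval −4.25 to −3.01), which is 12.4-fold, with an adjusted p of 0.0277 in limma. It read 292 and 550.4 in the null animals against 4907 and 5767 in the controls. Both differences were present in each sex, at 4.32 and 4.76 for St3gal4 and at −4.15 and −3.11 for Pla2g2a in the male and female pairs.

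Every other probe set had an adjusted p of 1 in limma, so the remaining named genes are given as values. Those with the smallest p and the same direction in both pairs come first. Among those higher in the null animals were Mmp7, the Paneth cell protease matrilysin, at 1.22 (SE 0.21), Reg1 at 1.5 (SE 0.31), the hormone gene Ghrl, which encodes ghrelin, at 1.70 (SE 0.38), and the crypt surface protein Cd24a at 0.62 (SE 0.13). Others were Gng3 at 1.31, Cilp2 at 1.22, Hcn3 at 1.07, Vill at 1.14, Spink4 at 0.61 and Agr2 at 0.62. Cyth3 gave 1.49 on 1 probe set and 0.03 on its other, and the other Agr2 probe set gave 0.27. The Ghrl controls had deposited intensities of 6.57 and 27.67, around the level of the St3gal4 controls. They are likewise not shown to lie above background, so the size of the Ghrl difference is uncertain. Values below 0 included the imino acid transporter Slc6a20a at −1.11 (SE 0.19), Cubn, the cubilin receptor for intrinsic factor, at −1.35 (SE 0.24), the peroxisomal thiolase Acaa1b at −1.34 (SE 0.23), the alcohol dehydrogenase Adh4 at −1.47 (SE 0.27) and Nr1i3, the nuclear receptor CAR, at −1.22 (SE 0.25). Further values were −1.20 for Aadac, −1.15 for Hsd17b2, −0.65 for Maoa, −1.04 for Abhd11os, −1.39 for Ces1e and −1.61 for the neurotensin gene Nts. Ces1e read 12.83 and 10.96 in the null animals, which are not shown to lie above background, so its size is uncertain too.

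limma thus called 1 probe set higher and 1 lower, and 480 of 15838 (3.03%) had an unadjusted p under 0.05, where 792 would be expected with no difference. That shortfall depended on the model, as 805 had such a p in limma with sex as a block. Across genes, which are not independent replicates, the differences of the male pair and the female pair had a correlation of −0.0235, and 48.2% of genes had the same sign in both. In all, 100 probe sets differed by at least 2-fold with the same sign in both pairs. With sex as a block 29 probe sets passed, 14 higher and 15 lower, both of the 2 calls among them. These 29 belonged to 25 named genes besides probe sets without a single gene, and among them were Reg3g (1.23, adjusted p = 0.00042 in limma), Pla2g2e (1.92, 0.00345), Mmp7 (1.22, 0.0127), Rdh7 (−1.69, 0.0184), Cubn (−1.35, 0.0216) and Slc6a20a (−1.11, 0.0485). Aadac (adjusted p = 0.0212 in limma), Cyth3 (0.0216), Cilp2 (0.0276), Adh4 (0.0372), Acaa1b (0.0372) and Aldh1a1 (−0.72, 0.0429) passed in that fit too. The count depended on single arrays: it was 35 without the male null animal, 10 without the female null animal, 3 without the female control and 0 without the male control, where 205 probe sets had an unadjusted p under 0.05. Pla2g2a missed the threshold without the female control (adjusted p = 0.0768 in limma), without the male control (0.242) and without a trend in the prior (0.228), and St3gal4 missed it without the male control (0.108), with the differences themselves at −3.75, −3.51, −3.63 and 4.47.

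Of the gene lists of absorptive enterocytes, 3 passed as lower in the null animals with the preset correlation, while lipid absorption and chylomicron assembly did not pass (median −0.02, adjusted p = 0.286 in camera). Nutrient transporters had a median log2 difference of −0.17 over 18 members, 14 of them lower, and brush border digestive enzymes one of −0.28 over 11 members, 10 of them lower. The adjusted p in camera was 4.99e-05 for both with the preset correlation, and 0.431 for transporters and 0.571 for enzymes as adjusted p with an estimated correlation. Of the transporters, 0 passed the threshold over all genes and 2 when adjusted over the list alone, Slc6a20a and the glutamate transporter Slc1a1, which differed by −0.94 (SE 0.21). No brush border enzyme passed either way, and the smallest p values belonged to the aminopeptidase Xpnpep2 at −0.85 and the endopeptidase Mme at −0.45. Brush border structure, 12 genes of the microvillus cytoskeleton, had a median of −0.14 with 9 lower (adjusted p = 0.0266, and adjusted p = 0.571 with an estimated correlation), with espin, Espn, at −0.56 and villin, Vil1, at −0.38, and no member past the threshold over all genes or adjusted over the list alone. In the male and female pairs the medians were −0.16 and −0.43 for transporters, −0.14 and −0.48 for enzymes and −0.025 and −0.29 for structure. On the same arrays the smooth muscle list stood at −0.22 in the male pair and 0.69 in the female pair.

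The list of fatty acid oxidation and ketogenesis passed as lower, with a median of −0.20 over 15 members and 14 of them lower. Acaa2, a mitochondrial thiolase, differed by −0.40 (SE 0.13) and the carnitine carrier Slc25a20 by −0.56 (SE 0.19). The list's adjusted p in camera was 3.45e-05, with adjusted p = 0.431 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. Xenobiotic metabolism had the lowest median of all lists tested, −0.40 over 25 members with 20 lower, at an adjusted p of 8.72e-06 in camera and adjusted p = 0.571 with an estimated correlation. Its smallest p values were those of Nr1i3 and of the aldehyde dehydrogenase Aldh1a1 at −0.72 (SE 0.17), and no member passed over all genes or adjusted over the list alone. The pair medians were −0.31 and −0.27 for fatty acid oxidation and −0.39 and −0.26 for xenobiotic metabolism, male before female. Without the female null animal the xenobiotic median was −0.081 (adjusted p = 0.178) and without the male control it was −0.087 (adjusted p = 0.19), so 2 arrays decided that call. It was −0.705 without the male null animal and −0.638 without the female control.

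The goblet cell list passed as higher in the null animals with the preset correlation. All 9 members were higher, in both pairs, with a median of 0.37, which was 0.38 in the male pair and 0.30 in the female pair. The adjusted p in camera was 5.3e-07, with adjusted p = 0.431 with an estimated correlation. None passed over all genes and 2 passed adjusted over the list alone, Agr2, a disulfide isomerase of mucin folding, at 0.62 (SE 0.14) and the secreted peptide gene Spink4 at 0.61 (SE 0.13). The other Agr2 probe set gave 0.27, with 0.548 in the male pair and −0.009 in the female pair. Paneth cell genes went both ways, and with 4 members the list was too short to test as a whole. Pla2g2a was at −3.63, the lysozyme gene Lyz1 at −0.21, the lectin gene Itln1 at 0.26 and Mmp7 at 1.22, and 1 of the 4 passed over all genes and all 4 adjusted over the list alone. Enteroendocrine genes had a median of 0.08 over 16 members (adjusted p = 0.426), with Ghrl at 1.70 and Nts at −1.61 being the 2 that passed adjusted over the list alone and 0 over all genes.

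The epithelial defence and inflammation list passed as higher, with a median of 0.22 over 12 members, 8 of them higher. The adjusted p was 0.0138 in camera, with adjusted p = 0.571 with an estimated correlation. None passed over all genes, and the 4 that passed adjusted over the list alone belonged to the Reg family of secreted lectins. Of these, Reg1 at 1.5, Reg3g at 1.23 and Reg3b at 0.52 were higher and Reg3a at −0.78 was lower in both pairs. The list median was 0.47 in the male pair and −0.02 in the female pair, and it was 0.034 without the male null animal and 0.366 without the female null animal. Without the filter on dim probe sets it was 0.074 and the call was lost (adjusted p = 0.0761).

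The T cell and intraepithelial lymphocyte list passed as lower in the null animals with the preset correlation, with all 9 members lower in both pairs. The median was −0.38, from −0.46 in the male pair and −0.26 in the female pair, at an adjusted p of 0.000159 in camera and adjusted p = 0.431 with an estimated correlation. Cd7 differed by −0.84 (SE 0.22) and the granzyme gene Gzma by −0.61 (SE 0.27), and no member passed over all genes or adjusted over the list alone. The smooth muscle list passed as higher over the 4 arrays, with a median of 0.29 and 10 of 11 members higher, of which 4 had the same sign in both pairs (adjusted p = 0.00158 in camera, and adjusted p = 0.571 with an estimated correlation). Lmod1 differed by 1.05 (SE 0.27), with control intensities of 13.27 and 18.14 that are not shown to lie above background. Des differed by 0.50 (SE 0.23), and 0 members of the list passed over all genes or adjusted over the list alone. The male pair did not share that direction, with a median of −0.22 against 0.69 in the female pair. The median over the remaining arrays was −0.104 (adjusted p = 0.722) without the female null animal and 0.173 (adjusted p = 0.0753) without the female control. Lists of other cell types did not pass in camera: B cells and plasma cells had a median of 0.22 (adjusted p = 0.436), myeloid cells 0.18 (0.146), fibroblasts 0.12 (0.412), endothelium 0.23 (0.137) and pancreatic acinar cells 0.21 (0.101). With sex as a block the pancreatic acinar list passed, at an adjusted p of 0.0425, against adjusted p = 0.719 with an estimated correlation and no block. Their members with the smallest p were Cd22 at −0.70 and Ms4a1 at 0.81 for B cells, Cd14 at 0.83 and Lyz2 at −0.17 for myeloid cells, and Col1a2 at 0.41 and Dcn at 0.27 for fibroblasts. Endothelial Egfl7 stood at 0.50 and Kdr at 0.37, and the pancreatic genes Cela3b and Cpa1 at 0.48 and 0.475. Enteric neurons and glia, with Prph at 0.21 and Uchl1 at −0.06, and red blood cells, with Hba-a1 at 0.27 and Slc4a1 at 0.13, had 2 members each and were not tested as lists, with medians of 0.08 and 0.20.

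**Figure D2:**
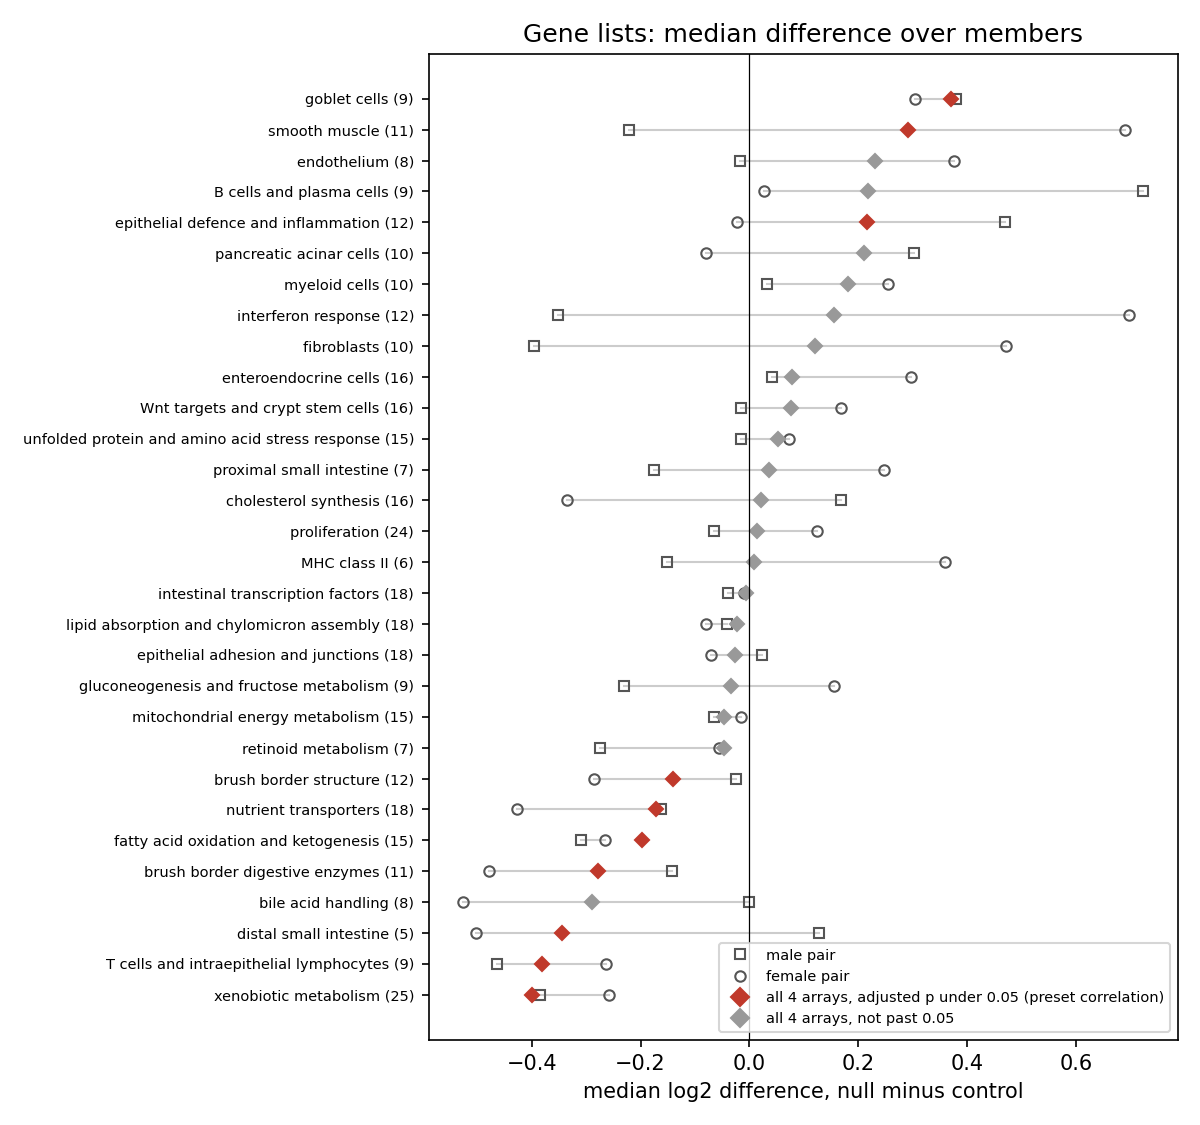
Median log2 difference, null minus control, over the members of each gene list tested, with the number of members in brackets. Diamonds are all 4 arrays, red where camera's adjusted p with a preset correlation was under 0.05, and open squares and circles are the male and the female pair. The goblet list lies at 0.38 and 0.30 in the 2 pairs, while smooth muscle lies at −0.22 and 0.69.

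The list of distal small intestine genes passed as lower over the 4 arrays, with a median of −0.34 and all 5 members lower, of which 2 had the same sign in both pairs (adjusted p = 0.00265 in camera, and adjusted p = 0.447 with an estimated correlation). Of these, Nts at −1.61 passed adjusted over the list alone and none over all genes, and Osr2 was at −0.57. The median was 0.13 in the male pair and −0.50 in the female pair, and it was 0.022 without the female control (adjusted p = 0.168) and −0.24 without the female null animal (adjusted p = 0.0567). Without the filter on dim probe sets it was −0.107 and the call was lost (adjusted p = 0.0971). Proximal genes had a median of 0.04 (adjusted p = 0.674), with Ghrl at 1.70 the 1 member past the threshold adjusted over the list alone and Gip at −0.61. Of the 5 distal members 4 are also in another list, as are 4 of the 7 proximal ones. Nts and Ghrl are enteroendocrine members too, so these lists are not separate evidence. Of the 18 members for lipid absorption and chylomicron assembly, 8 were higher and 10 lower, with the fatty acid transporter Slc27a4 at −0.60 and Fabp1 at −0.21.

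Other metabolic lists did not pass in camera on the 4 arrays without a block. Bile acid handling had a median of −0.29 over 8 members (adjusted p = 0.286), with the bile acid receptor gene Nr1h4 at −0.67 and Abcc3 at −0.35. Retinoid metabolism had one of −0.05 over 7 members (adjusted p = 0.101, 0.021 with sex as a block, where the list passed, and adjusted p = 0.571 with an estimated correlation and no block), and 2 members passed adjusted over the list alone, Aldh1a1 at −0.72 and Rdh7 at −1.69. Gluconeogenesis and fructose metabolism stood at −0.03 (adjusted p = 0.165), with Gpd1 at −0.46 and Tkfc at −0.39, and mitochondrial energy metabolism at −0.05 (adjusted p = 0.307), with Ndufs1 at −0.36 and Idh3a at −0.31. Cholesterol synthesis had a median of 0.02 but a mean of −0.07, and camera pointed down (adjusted p = 0.426), with Msmo1 at −0.62 and Idi1 at −0.41.

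Lists of cell identity and state gave small medians, none past the threshold in camera. Intestinal transcription factors stood at −0.006 over 18 members (adjusted p = 0.96), with Elf3 at 0.59 and Ppara at −0.63. Epithelial adhesion and junctions stood at −0.03 (adjusted p = 0.449), with Dsp at −0.34 and Epcam at −0.12. Wnt targets and crypt stem cells had a median of 0.08 (adjusted p = 0.175), with the cotransporter Slc12a2 at 0.64 and Msi1 at 0.77, and proliferation one of 0.01 over 24 members (adjusted p = 0.566), with Plk1 and Mcm3 at 0.45 each. Unfolded protein and amino acid stress genes stood at 0.05 (adjusted p = 0.672), with Chac1 at 0.80 and Trib3 at 0.54, interferon response at 0.16 (adjusted p = 0.137), with Cxcl10 at 0.65 and Irf7 at 0.49, and MHC class II at 0.01 (adjusted p = 0.729), with H2-Ab1 at 0.18 and Cd74 at 0.16. Control intensities of 17.66 and 16.95 for Chac1 and of 21.31 and 19.92 for Cxcl10 are not shown to lie above background. In the null animals Cxcl10 read 22.43 and 63.72. The other Trib3 probe set gave 0.063.

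**Figure D3:**
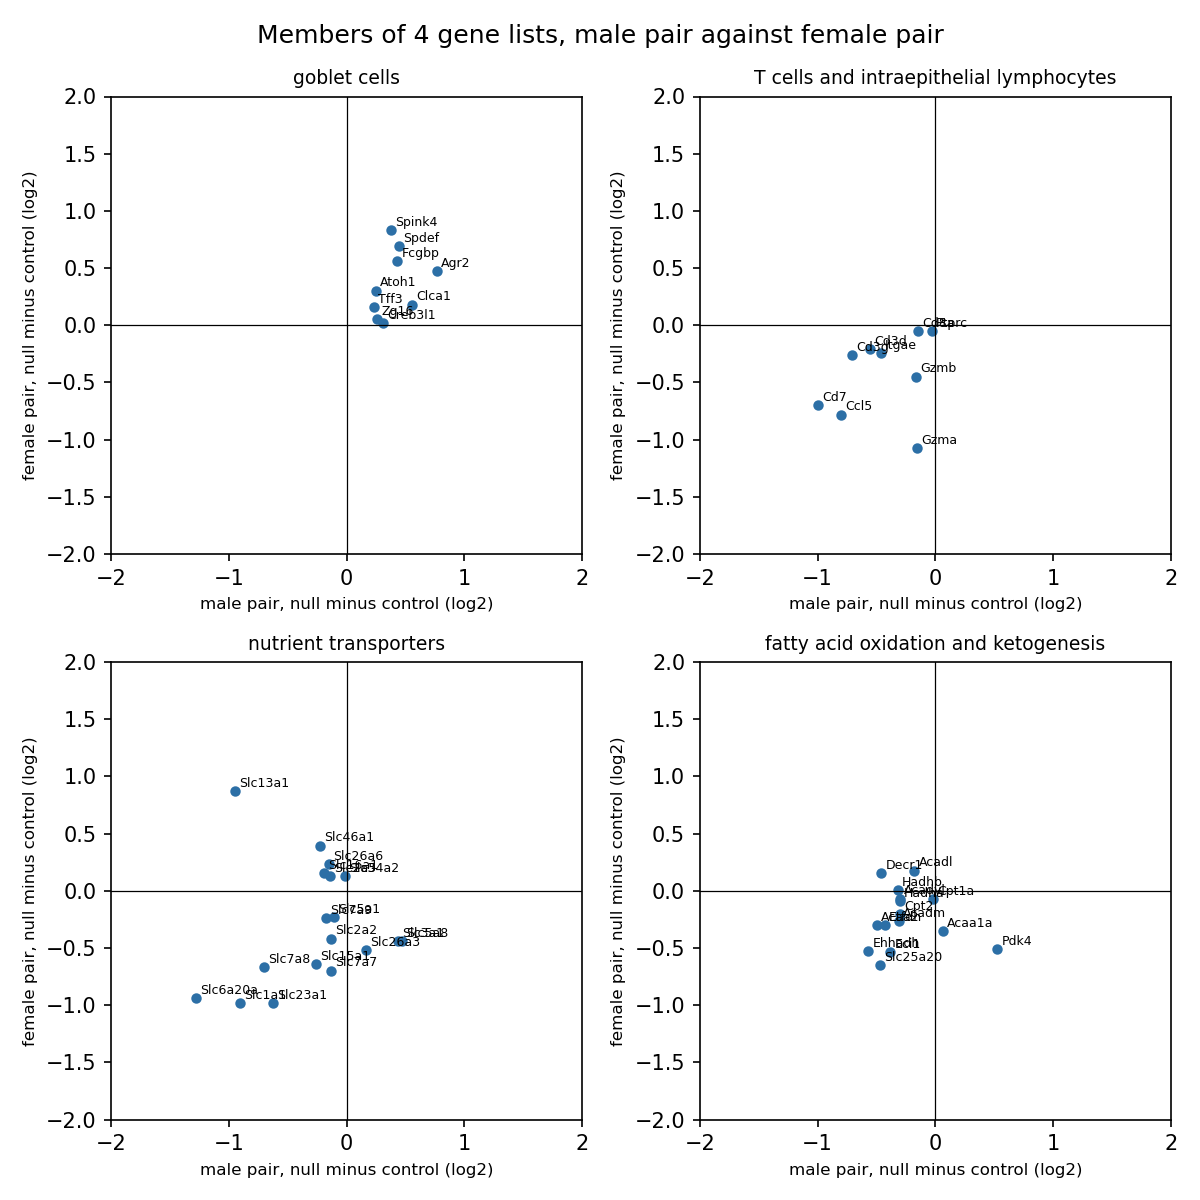
Log2 difference, null minus control, of each member of 4 gene lists in the male pair (horizontal) and the female pair (vertical). All 9 goblet genes lie above 0 on both axes and all 9 T cell genes below 0, while 9 of 18 nutrient transporters and 10 of 15 fatty acid oxidation genes have the same sign in both pairs.

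In camera, 10 of 30 lists passed, 3 higher and 7 lower, with a preset correlation of 0.01. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05. That run rests on 2 residual degrees of freedom, so its count of 0 does not show whether correlation between genes explains the calls. Goblet cells, T cells, nutrient transporters and fatty acid oxidation kept their calls whichever array was left out, with medians from −0.307 to −0.183 for transporters and from −0.317 to −0.185 for fatty acid oxidation, while brush border enzymes lost it without the female null animal (−0.087, adjusted p = 0.253) and brush border structure without the female null animal (−0.087, adjusted p = 0.431) and without the female control (−0.047, adjusted p = 0.469).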

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

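Beforehand, the direction in the 2 pairs was fixed only as part of the rule for named genes. The rule for listing results here first had size limits chosen after the data were seen, and these were then removed. Chosen only after the result was seen were the tests of Paneth genes and of the genes around Pla2g2a. So were those of cell composition, of position along the gut and of other splits of the arrays. A result is listed here when the male and the female pair moved in opposite directions, which was so for 15 of 30 lists and 8 of 80 named genes. Some named genes were required to have the same direction in both pairs, and others were taken by smallest p. The share of 8 in 80 is thus partly set by that choice and does not measure how well the pairs agree. Across all genes tested, 48.2% had the same sign in both pairs. Each pair is 1 animal against 1, so the difference between the pairs was not tested.

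Among the cell type lists with opposite signs were 3 of the gut wall. The female pair difference minus the male one was 0.91 for smooth muscle, 0.87 for fibroblasts and 0.39 for endothelium, with the female pair above 0 and the male pair below 0 in each, and −0.38 for pancreatic acinar genes, where the order was the reverse. Immune response lists went the same way as the wall, at 1.05 for interferon response and 0.51 for MHC class II, and epithelial defence went the other way at −0.49. Along the gut, the value was 0.42 for proximal and −0.63 for distal genes. Among metabolic lists it was −0.50 for cholesterol synthesis and 0.39 for gluconeogenesis and fructose metabolism. The remaining lists were closer, at −0.09 for adhesion and junctions, 0.18 for Wnt targets, 0.19 for proliferation and 0.09 for the unfolded protein response. Single genes gave −0.78 for Hnf4a, −2.04 for Cd22, −0.29 for Uchl1, −1.04 for Slc4a1, −1.10 for Cpa1, −1.19 for Mcm3, 1.07 for Irf7 and 0.56 for Cd74.

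Among the named genes, St3gal4 and Pla2g2a had the largest differences in both pairs, although Ghrl reached 2.46 in the female pair. Fewer Paneth cells in the null animals would lower the whole Paneth list, but the other 3 members had a median of 0.26 (range −0.21 to 1.22), which argues against it for Pla2g2a. A chromosome segment from another mouse strain is a candidate explanation, since strains are known to differ at Pla2g2a; of the 20 nearest tested genes, 1 around Pla2g2a (Pla2g2e, which was higher) and 0 around St3gal4 had an unadjusted p under 0.05 with one direction in both pairs. The count of 0, named beforehand as evidence against a segment, excludes nothing after all, because 52.6% of 10000 random windows also held 0 and 47.4% held at least 1. An effect of HNF4 loss on these 2 genes stays open and cannot be told apart from a strain difference with 2 animals per group.

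The goblet list median was above 0 and the nutrient transporter list median below 0 in both pairs, although 9 of 18 transporters had the same sign in both. A lower share of enterocytes would be expected to raise other cell types alike. The goblet median exceeded the T cell median by 0.75 (95% resampling interval over genes 0.50 to 1.18). These 2 lists were compared after one had been seen higher and the other lower, so that interval cannot decide the question. The T cell median was below 0, but its list includes lymphocytes that lie within the epithelium. Over the 4 arrays, every other tested list of a cell type outside the enterocytes had a median above 0. These medians ran from 0.08 for enteroendocrine cells to 0.29 for smooth muscle. The enteroendocrine, B cell and myeloid lists were above 0 in both pairs. Below 0 in the male pair were smooth muscle (−0.221), fibroblasts (−0.395) and endothelium (−0.018), and in the female pair pancreatic acinar genes (−0.079). Other cell types were thus not raised alike in both pairs. A lower share would also be expected to lower the lipid absorption and chylomicron list of enterocytes. Its median was −0.023, with 8 members higher and 10 lower, and −0.041 and −0.079 in the male and female pairs. With lists going both ways, a lower share of enterocytes stays open. Tissue taken from another position along the gut could move both lists: the distal minus proximal median was −0.75 in the female pair (interval −2.11 to −0.36) and 0.30 in the male pair (interval −1.91 to 0.99), so it remains open. No list held its call with an estimated correlation, but that run, with 2 residual degrees of freedom, could hardly call any list. The cause of the pattern stays open. Genotype differences between the controls, and litter, were not tested.

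The 3 splits of 4 arrays into groups of 2 are too few to give a share under 0.05. The real split called 2 probe sets and the highest other 6, so that 2 of the 3 splits called as many, and the real split called 10 lists and the highest other 5, so that 1 of the 3 called as many. Of the 10 lists, xenobiotic metabolism was also called in the split by sex and smooth muscle in the remaining split. That remaining split, which mixes sex and group, called 1 probe set and 5 lists. In limma it had 459 probe sets at an unadjusted p under 0.05. The split with 6 calls is that of males against females, with 1207 probe sets at an unadjusted p under 0.05 against 480, which points to a structure of the samples by sex or by whatever else differs between the 2 pairs, and with sex as a block 29 probe sets passed.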

How the results depend on the processing

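All alternatives were planned. The count of 2 probe sets was the same with either pseudocount, with deposited or median-centred intensities, with no or a 50% filter, with array weights, at an adjusted p under 0.1 and with a 1.5-fold limit. It became 29 with sex as a block and 1 without a trend in the prior, where the cause was not tested, and ranged from 0 to 35 when 1 array was left out, which also leaves a group with 1 animal assumed to vary like the other group. List calls numbered 8 to 12 under the other settings, 6 to 14 when 1 array was left out and 0 with an estimated correlation. Brush border structure lost its call with median centring (adjusted p = 0.0572) and without a trend (0.0668), and epithelial defence (0.0761) and distal genes (0.0971) without a filter; these causes were not tested. With the 50% filter the distal list kept fewer than 5 members and was not tested. Of list results under settings other than leaving out an array, 273 were the same, 14 weaker, 2 stronger and 8 reversed; of named genes, 659, 1, 11 and 4. Unfiltered, 718 of 22626 probe sets had an unadjusted p under 0.05.

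Under settings other than leaving out an array, the medians that reversed were of lists that had not passed: with deposited intensities, cholesterol synthesis −0.017, proliferation −0.034, MHC class II −0.032 and proximal −0.011; with the 50% filter, enteroendocrine −0.037 and MHC class II −0.009; with the mean of all probe sets, cholesterol synthesis 0 after rounding and proliferation −0.018. Other probe sets gave −0.058 for Cela3b and −0.23, −0.096 and −0.51 for Mcm3. The cause was not tested. Leaving out 1 array at a time gave these ranges of log2 difference across 0. Hnf4a: −0.046 to 0.54 over its probe sets and −0.081 to 0.57 on its brightest; Hnf4g −0.014 to 0.32, Cd22 −1.67 to 0.28, Ms4a1 −0.30 to 1.92, Prph −0.085 to 0.51, Uchl1 −0.15 to 0.036, Slc4a1 −0.33 to 0.60, H2-Ab1 −0.039 to 0.39 and Cd74 −0.15 to 0.46. List medians ran from −0.071 to 0.35 for enteroendocrine, −0.40 to 1.01 for B cells, −0.104 to 0.58 for smooth muscle, −0.30 to 0.46 for fibroblasts, −0.18 to 0.50 for pancreatic acinar, −0.12 to 0.003 for lipid absorption, −0.082 to 0.033 for adhesion, −0.14 to 0.13 for cholesterol synthesis, −0.33 to 0.026 for bile acids, −0.29 to 0.22 for gluconeogenesis, −0.22 to 0.006 for retinoids, −0.051 to 0.01 for transcription factors, −0.12 to 0.22 for proliferation, −0.053 to 0.18 for the unfolded protein response, −0.24 to 0.76 for interferon, −0.086 to 0.092 for MHC class II, −0.057 to 0.18 for proximal and −0.58 to 0.022 for distal genes. The groups share no replicate number, but adjacent numbers join the null and the control animal of each sex. The block on sex sets those same animals against each other, so it cannot be told apart from a pairing by adjacent number. Besides the pancreatic acinar and retinoid lists, which it added, the block changed no list call. The table holds no background signal, so how far dim probe sets lie above it is unknown.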

Other observations

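The test of genes around Hnf4a was written before its result was seen, while the sex term described next was read only after the fit with sex as a block had been made. In that fit, 84 probe sets differed between males and females, 74 of them with a single gene, 49 higher in males and 25 lower. Genes higher in the males, named after the result was seen and not tested as a group, included Cyp2b10, a cytochrome of drug metabolism, by 2.47 (SE 0.25, adjusted p = 0.00206 in limma), Gstm1, a glutathione transferase, by 1.58 (SE 0.14, 0.000995) and Cyp3a11 by 0.87 (SE 0.10, 0.00295). Of the probe sets past the threshold, 8 were of immunoglobulin genes or of the J chain gene and all 8 were higher in the males, such as Jchain at 1.07 and Igha at 0.77. This did not hold for B cell genes in general: the brighter Ighm probe set measured 8.985 and 7.548 in the males against 9.143 and 9.72 in the females, and Cd79a, Cd79b, Ms4a1 and Pou2af1 were also lower in the males on average. Lower in the males were Xist at −4.60, the lymphoid cytokine gene Ltb at −2.41 and the claudin gene Cldn2 at −1.38. Genes of the major histocompatibility complex went both ways, with H2-Bl at 2.17 and H2-D1 at −0.86, and a single probe set of the proteasome gene Psmb1 stood 3.46 higher in the males. Each sex is 2 animals, 1 null and 1 control, and sex cannot be told apart from anything else that the 2 animals of a sex shared.

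A floxed or deleted allele carries flanking chromosome from the strain in which it was made, and the genes next to Hnf4a were counted with that in view. Of the 20 tested genes nearest to Hnf4a, 2 (Ada and Ccn5) had an unadjusted p under 0.05 with one direction in both pairs. At least as many occurred in 13.3% of 10000 random windows, whose 95th percentile was 2, so the count does not stand out. By the labels, both animals of the male pair carried a loxP allele over a minus allele, and only the female control carried a wild-type allele. A segment carried with these alleles is not expected to differ within the male pair, while the count required the same direction in both pairs. The count of 2 therefore does not test for such a segment.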
